A study of Arabidopsis thaliana with 12 samples.

How the data were processed

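Transcript levels were measured on 12 single-colour Affymetrix-type arrays, each hybridised with biotin-labelled RNA from complete 21-day-old Arabidopsis thaliana plants. The arrays form 4 groups of 3: wild-type Col-0 untreated, Col-0 given 20 µM t-zeatin for 3 h, plants overexpressing ARR22 (ARR22-ox) untreated, and ARR22-ox given the same t-zeatin treatment. The untreated plants were labelled as having no treatment, so they are not a mock treatment. The labels give no growth batch, harvest date, hybridisation batch or pairing, so a batch that follows a group cannot be told apart from that group. Sample titles are numbered in sequence within each group. The 3 Col-0 t-zeatin titles, and only those, carry a suffix whose meaning is not given. Replicate numbers follow the order of the samples and pair nothing. The labels do not say whether the 3 arrays of a group came from different plants, and every p-value measures only the spread between these arrays.

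The deposited values are array intensity per probe set on a linear scale, and the submitters' notes name MAS5, without a version, as the software. The authors scaled each array to the same level: the mean of its signals, after the lowest and highest 2% were trimmed, was 100 on all 12 arrays. The table held 22810 probe sets, of which 64 were control probe sets. Detection calls were not used here. No pair of arrays was identical. For arrays, the number per group limits the precision.

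Signals were taken as deposited and converted to log2. Control probe sets were left out of the tests, and probe sets whose mean log2 signal over all 12 arrays lay at or above the 40th percentile were kept. This left 13648 probe sets, and the lowest kept mean corresponded to a signal of 24.3. Gene names came from the given table for the array, which pairs 13513 probe sets with 1 gene, 503 with several and 8730 with none. A gene was named only from a probe set paired with 1 gene, and the brightest of several such probe sets stood for it. Of 65 genes with several tested probe sets, 1 had calls in opposite directions in the ARR22-ox response and 1 in the untreated genotype comparison. Of the probe sets with 1 gene, 13436 had their gene in the given genome annotation. No coordinates are printed, because probe positions were not mapped.

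A linear model with the 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance on the mean signal. The 5 comparisons were the t-zeatin response in Col-0, the response in ARR22-ox, the difference of these responses, and ARR22-ox against Col-0 without and with t-zeatin. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13648 probe sets. Changes are log2 differences with the model's standard error, and signals are means with standard deviations over 3 arrays.

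The genes named are, for both responses and the untreated genotype comparison, the 10 largest rises and 10 largest falls among called probe sets with 1 named gene. All 3 values of 1 group had to lie beyond all 3 of the other, and the higher group mean had to reach the median signal of 39.9. The other comparisons took 5 and 5 by the same rule, and ARR22 and the members of the gene lists were added. The comparisons, the naming rule, the filter and 32 gene lists were fixed before the data were examined. These lists cover cytokinin signalling and metabolism, other hormones, stress, nutrients, cell walls, the clock and organ markers. Only 17 of them had a tested member, and 6 had the 3 tested members needed for a list test. The lists name more genes than were tested. A gene went untested when the given table paired no probe set with it alone or its probe set lay below the filter. Counts of members thus cover only the tested genes, and an untested gene is not shown to be unexpressed. A further 23 lists, of large gene families and complexes, were written after the gene names and the correlations between arrays had been seen and before any comparison was run, and 22 of them could be tested. These are called added lists.

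Lists were tested against all other genes with camera in limma at a preset correlation of 0.01, with p-values adjusted over the lists of the same kind in a comparison. The test was run again with the correlation estimated from the arrays, and with fry, which asks whether the members of a list move, on balance, one way. Called members of the fixed lists were also counted after adjustment over their list alone. With at least 44.8% of the tested probe sets called in each comparison, that step could hardly lose a call. It therefore adds no support to any list below. The method was tested on simulated arrays: independent normal noise around the Col-0 untreated means, with spreads from the real arrays and known changes planted in some probe sets. With a log2 change of 1, it recovered 86% of the planted changes in the Col-0 comparison and 56% in the difference of responses. At 0.5 these shares were 36% and 16%, and 3.45% and 4.55% of the calls were false. The simulated arrays held no outlying array, no correlation between probe sets and few changed probe sets. These shares may therefore not carry over to the real arrays.

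Alternatives were quantile normalization, arrays set to the same median, an offset of 10.6 (the 25th percentile of the signals) before log2, no filter, a stricter filter, no variance trend, array weights, only the 6 arrays compared, and each array left out in turn. Calculations used Python 3.11.15 and pandas 2.3.3, and figures matplotlib 3.10.9.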

Results

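The 12 arrays compared wild-type Col-0 plants with plants overexpressing ARR22, a type-C response regulator, each untreated or given 20 µM t-zeatin, a natural cytokinin, for 3 h. Each of the 4 groups had 3 arrays of complete 21-day-old plants. Pearson correlations across probe sets within a group lay between 0.988 and 0.991 for the other 3 groups and between 0.927 and 0.990 for ARR22-ox untreated. ARR22-ox untreated replicate 3 stood apart, with a mean correlation of 0.927 to its own group. On that array the 3'/5' signal ratio was 1.82 for the GAPDH control and 3.47 for the second actin control, against highest values of 1.09 and 1.38 on the other arrays. It is 1 of the 3 arrays behind every ARR22-ox untreated mean below.

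The first question was whether the arrays labelled ARR22-ox carried more ARR22 transcript. RR22 (AT3G04280, ARR22) had a signal of 3255 ± 402 in ARR22-ox untreated and 2892 ± 209 in ARR22-ox t-zeatin (SD, n = 3 arrays per group). In Col-0 it was 1.13 ± 0.69 untreated and 0.518 ± 0.105 after t-zeatin, far below the lowest kept mean of 24.3, so no change within Col-0 was read from it. The log2 difference between untreated groups was 11.65 ± 0.31 (SE, adjusted p = 1.64e-10), and every ARR22-ox array, lowest signal 2752, exceeded every Col-0 array, highest signal 1.92. The size of this difference depends on the dim Col-0 values: with an offset before log2 it was 8.11.

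**Figure D1:**
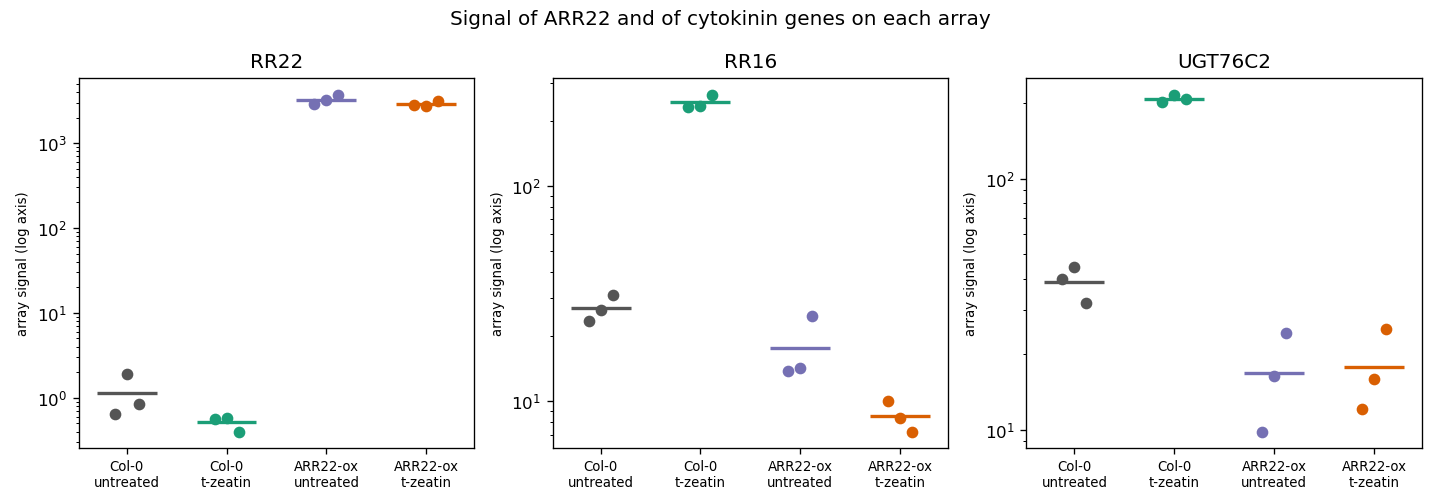
Array signal on a log axis for RR22 (ARR22), RR16 (ARR16) and UGT76C2 in the 4 groups; points are the 3 arrays of a group and bars their means. RR22 was above 2750 on each ARR22-ox array and below 2 on each Col-0 array, and RR16 rose to a mean of 244 after t-zeatin in Col-0 and stood at a mean of 8.55 in ARR22-ox t-zeatin.

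The second comparison asked which transcripts changed after t-zeatin in wild-type plants. RR16 (AT2G40670), the type-A response regulator ARR16 of a family known for rapid induction by cytokinin, rose 9.04-fold from 27.1 ± 3.74 to 244 ± 17 (SD, n = 3; log2 change 3.18 ± 0.22, SE; adjusted p = 3.54e-07). UGT76C2 (AT5G05860), a glucosyltransferase that conjugates cytokinins, rose 5.44-fold from 38.7 ± 6.36 to 209 ± 6.52. EXO (AT4G08950), a cell wall gene known to be induced by brassinosteroids, fell 7.13-fold from 1867 ± 77.2 to 262 ± 11. The transcription factor gene WRKY22 fell 4.87-fold, from 126 ± 2.48 to 25.9 ± 2.22.

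Genes of protein synthesis rose together in Col-0. In the added list of cytosolic ribosomal proteins, 105 of 114 tested members rose and none fell, with a median log2 change of 0.54 (camera adjusted p = 7.86e-26, or adjusted p = 0.0424 with an estimated correlation). The largest changes in that list, picked after the values were seen, were 2.13 for AT2G32220 and 1.97 for AT5G39850. Of 9 subunits of the nuclear RNA polymerases, 7 rose and none fell (median 0.85, adjusted p = 0.000291, or adjusted p = 0.0299 with an estimated correlation). NRPA1 and NRPA2, the largest subunits of RNA polymerase I, which transcribes ribosomal RNA, rose by 2.34 and 1.81. Of 7 tubulin genes 6 rose, among them TUB1 by 1.02 (list adjusted p = 0.0145, or adjusted p = 0.495 with an estimated correlation).

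Of 30 added nuclear-encoded photosynthesis genes, 24 fell in Col-0 and none rose (median -0.39, adjusted p = 1.03e-07, or adjusted p = 0.00776 with an estimated correlation). PORB, an enzyme of chlorophyll synthesis, fell from 1441 ± 39.5 to 1020 ± 61.6, and LHCB4.2, a light-harvesting protein gene, from 2406 ± 61.6 to 1751 ± 88.6. Autophagy genes mostly fell as well, 6 of 10 with 1 rise (median -0.34, adjusted p = 0.0249, or adjusted p = 0.495 with an estimated correlation).

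Of the fixed lists, the touch- and wound-induced genes moved down in Col-0. STZ (AT1G27730), a zinc finger factor of stress responses also called ZAT10, fell from 317 ± 7.36 to 88.9 ± 4.74, and CML38, a calmodulin-like gene, from 165 ± 14.3 to 39.6 ± 7.22. The third tested member, WRKY53, had a change of -0.36 that did not pass. The list's median was -1.83 (camera adjusted p = 0.0343, or adjusted p = 0.141 with an estimated correlation), with 2 members down also when adjusted over the list alone. That adjustment could hardly lose a call, here or in the comparisons below. Among hormone and defence genes, PDF1.2, a plant defensin gene, fell by 1.14, SAG101 by 1.12 and WES1, an auxin-conjugating enzyme also called GH3.5, by 1.04 on the log2 scale. Among the fixed lists with 3 or 4 tested members, the changes of flavonoid genes (median -0.33), expansins (0.62), glutaredoxins (0.34) and root markers (-0.24) did not pass camera. The abscisic acid, cold and drought list (median -0.74, 2 of 3 down) did not pass either (adjusted p = 0.325), but passed without ARR22-ox untreated replicate 3 (adjusted p = 0.0222), which enters only the shared variance here.

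In all, 6113 probe sets were called in Col-0 by limma, 3231 up and 2882 down, and 1243 changed at least 2-fold. The other named rises ranged from 2.46 to 2.81, with AT2G18900 first and PPR596 last among AT3G59670, AT1G30960, AT4G04940, AT3G12860, AT1G10585 and AT5G51440. The other named falls ranged from -2.69 (AT5G10695) to -2.17 (AT1G02660) and included AT1G76960, AT5G25240, AT2G41640, AT2G44500, AT5G58120 and AT4G28085.

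The third comparison asked the same question in plants overexpressing ARR22. RR16 did not rise there: its signal went from 17.7 ± 6.27 to 8.55 ± 1.42 (log2 change -1.01 ± 0.22, SE; adjusted p = 0.0022), which lies below the lowest kept mean. The size of that change depends on dim signal, and it was -0.54 with the offset and -0.73 without ARR22-ox untreated replicate 3. UGT76C2 had 16.8 ± 7.21 untreated and 17.8 ± 6.71 after t-zeatin (log2 change 0.11, not called). The sign of that change turned under quantile normalization (-0.0356) and without ARR22-ox untreated replicate 1 (-0.23) or ARR22-ox t-zeatin replicate 3 (-0.18). STZ rose from 109 ± 30.4 to 617 ± 7.96 and CML38 from 45 ± 6.41 to 155 ± 5.47 (SD, n = 3).

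The touch- and wound-induced list moved up in ARR22-ox, with 3 of 3 members up, also when adjusted over the list alone (median 1.80, camera adjusted p = 0.0162, or adjusted p = 0.137 with an estimated correlation). The adjustment over the list alone adds no support, as it could hardly lose a call. The rise of WRKY53 (0.62) was lost when any of 9 arrays was left out (adjusted p up to 0.179), that is any array other than Col-0 t-zeatin replicates 1 and 2 and ARR22-ox untreated replicate 3. That call was also lost with quantile normalization (adjusted p = 0.0705) and with arrays set to the same median (0.0674). The same held without the filter on dim probe sets (0.0723) and with only the 6 arrays compared (0.114). The abscisic acid, cold and drought list did not pass in ARR22-ox, and its median turned from 0.36 to -0.56 without ARR22-ox untreated replicate 3. GH3.3, an auxin-conjugating enzyme, rose from 35.6 ± 9.65 to 202 ± 45.1, and PDF1.2 from 834 ± 356 to 1734 ± 32.6 (log2 change 1.17, or 0.74 without ARR22-ox untreated replicate 3). WRKY6, a senescence-associated transcription factor, rose by 1.49 and SAG101 by 0.74. Of 5 added plant U-box ligases 4 rose, among them PUB22 by 2.56 and PUB23 by 2.28 (list adjusted p = 0.015, or adjusted p = 0.198 with an estimated correlation), and without the filter on dim probe sets that list missed the threshold (adjusted p = 0.0653).

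The tested genes of anthocyanin synthesis fell in ARR22-ox. DFR (AT5G42800), which makes leucoanthocyanidins, fell from 859 ± 547 to 81.1 ± 3.39, UF3GT (AT5G54060) from 353 ± 161 to 43.7 ± 13.4, and AT4G14090, an anthocyanin glucosyltransferase, from 409 ± 182 to 39.2 ± 8.02. All 3 fell, also when adjusted over the list alone (median -3.08, camera adjusted p = 0.0162, or adjusted p = 0.209 with an estimated correlation). ARR22-ox untreated replicate 3 moved with this group: its DFR signal was 239 against 1066 and 1272 on the other arrays of its group, and without it the list's median was -3.73 and the change of DFR -3.85. In the added lists, 80 of 114 ribosomal protein genes fell and 3 rose (median -0.38, adjusted p = 2.83e-11, or adjusted p = 0.22 with an estimated correlation), and 86 fell and 8 rose without that array. Of 30 photosynthesis genes 25 fell and none rose (median -0.54, adjusted p = 5.97e-08, or adjusted p = 0.00698 with an estimated correlation). Of 13 serine carboxypeptidase-like genes 10 fell and 1 rose (adjusted p = 0.00367, or adjusted p = 0.102 with an estimated correlation). Of 8 glutathione transferase genes 5 fell and 1 rose (adjusted p = 0.0294, or adjusted p = 0.41 with an estimated correlation), and that call was lost without ARR22-ox untreated replicate 1 (0.077) or 2 (0.0755) and with the stricter filter (0.0684).

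Plastid-encoded transcripts rose in ARR22-ox, 32 of 64 with 3 falls (median 0.52, adjusted p = 7.03e-05, or adjusted p = 0.495 with an estimated correlation). The largest change was that of psaA, a photosystem I reaction centre gene, from 172 ± 109 to 2342 ± 179, and rpl16, of the plastid ribosome, rose from 170 ± 90.7 to 1666 ± 113. The array with the high 3'/5' ratios moved with this group: its psaA signal was 46.6 against 228 and 240, and without it the list had 34 rises and 10 falls with a median of 0.24, psaA a change of 3.32 in place of 4.095 and rpl16 2.90 in place of 3.49.

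In ARR22-ox 6863 probe sets were called, 3443 up and 3420 down, and 1561 changed at least 2-fold. Further named rises were AT3G23550 (3.98), AT5G48430 (3.89), AT2G22880 (3.75), AT2G38240 (3.67), AT3G60420 (3.43), AT5G62280 (3.42), CCR2, a lignin-pathway reductase also induced by stress (3.41), and AT5G62360 (3.27). Further named falls were AT1G22160 (-3.39), AT5G48490 (-3.20), the linker histone gene HIS1-3 (-3.09), AT5G57785 (-3.002), AT1G67750 (-2.73), AT2G20870 (-2.73) and AT5G62210 (-2.66). Without ARR22-ox untreated replicate 3 the change of AT2G38240 was 2.93, of CCR2 2.43 and of AT5G48490 -2.61. CCR2 stood at 4.07 without ARR22-ox untreated replicate 1 and at 2.33 with the offset.

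The fourth comparison asked whether the genotypes responded differently, and tested the difference of the responses itself, ARR22-ox minus Col-0. RR16 differed by -4.18 ± 0.31 (SE, n = 3 arrays per group; adjusted p = 5.88e-07) and UGT76C2 by -2.34 ± 0.43. With the offset these differences were -3.30 and -2.10. EXO, which fell in Col-0, rose in ARR22-ox from 148 ± 73.3 to 467 ± 13.2, a difference of 4.60 ± 0.32. STZ differed by 4.37 and CML38 by 3.87, both down in Col-0 and up in ARR22-ox. AT1G47400, a small peptide gene known to be induced by iron deficiency, rose in Col-0 from 51.8 ± 7.09 to 139 ± 8.91 and fell in ARR22-ox from 2208 ± 415 to 448 ± 9.43.

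Of 114 ribosomal protein genes, 113 had a lower response in ARR22-ox than in Col-0 and none a higher one (median difference -0.92; camera adjusted p = 9.29e-31, or adjusted p = 0.0608 with an estimated correlation). The same held for 8 of 9 RNA polymerase subunits (median -0.94, adjusted p = 0.00283, or adjusted p = 0.0608 with an estimated correlation). Of 7 tubulin genes 6 had a lower and 1 a higher response (adjusted p = 0.0246, or adjusted p = 0.411 with an estimated correlation), and without ARR22-ox untreated replicate 3 that list missed the threshold (adjusted p = 0.0523). The touch- and wound-induced list had 3 of 3 higher responses in ARR22-ox, also when adjusted over the list alone (median 3.87, adjusted p = 0.00619, or adjusted p = 0.0637 with an estimated correlation). The call of WRKY53 among them (0.98) was lost without Col-0 untreated replicate 1 or 2, Col-0 t-zeatin replicate 1 or 3, ARR22-ox untreated replicate 2 or ARR22-ox t-zeatin replicate 1 or 3 (adjusted p from 0.0511 to 0.0747), and without the filter on dim probe sets (0.0506). Plastid-encoded genes had 17 higher responses of 64 and 1 lower (median 0.42, adjusted p = 0.00283, or adjusted p = 0.654 with an estimated correlation; 0.0737 by fry), and without ARR22-ox untreated replicate 3 they had 26 higher and 9 lower with a median of 0.25. Of 5 U-box ligases 3 responded more in ARR22-ox (adjusted p = 0.0123, or adjusted p = 0.165 with an estimated correlation). All 3 tested anthocyanin genes had a lower response in ARR22-ox (median -2.59), but the list missed the threshold (adjusted p = 0.0981) unless ARR22-ox untreated replicate 3 was left out (adjusted p = 0.00662). The call of DFR among them (-1.87, or -2.63 without that array) was lost without replicate 1 or 2 of Col-0 untreated, Col-0 t-zeatin or ARR22-ox untreated, or without ARR22-ox t-zeatin replicate 1, 2 or 3 (adjusted p from 0.0504 to 0.0659). The photosynthesis list, with 2 higher and 6 lower, did not pass (median -0.02, adjusted p = 0.782), and had 6 higher and 8 lower without ARR22-ox untreated replicate 3. The expansins (median -1.12, 3 of 4 lower), the abscisic acid list (0.91, or 0.44 without ARR22-ox untreated replicate 3) and the glutaredoxins (0.63) did not pass either, nor did the root markers, whose median (-0.05) and mean (0.18) differ in sign.

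**Figure D2:**
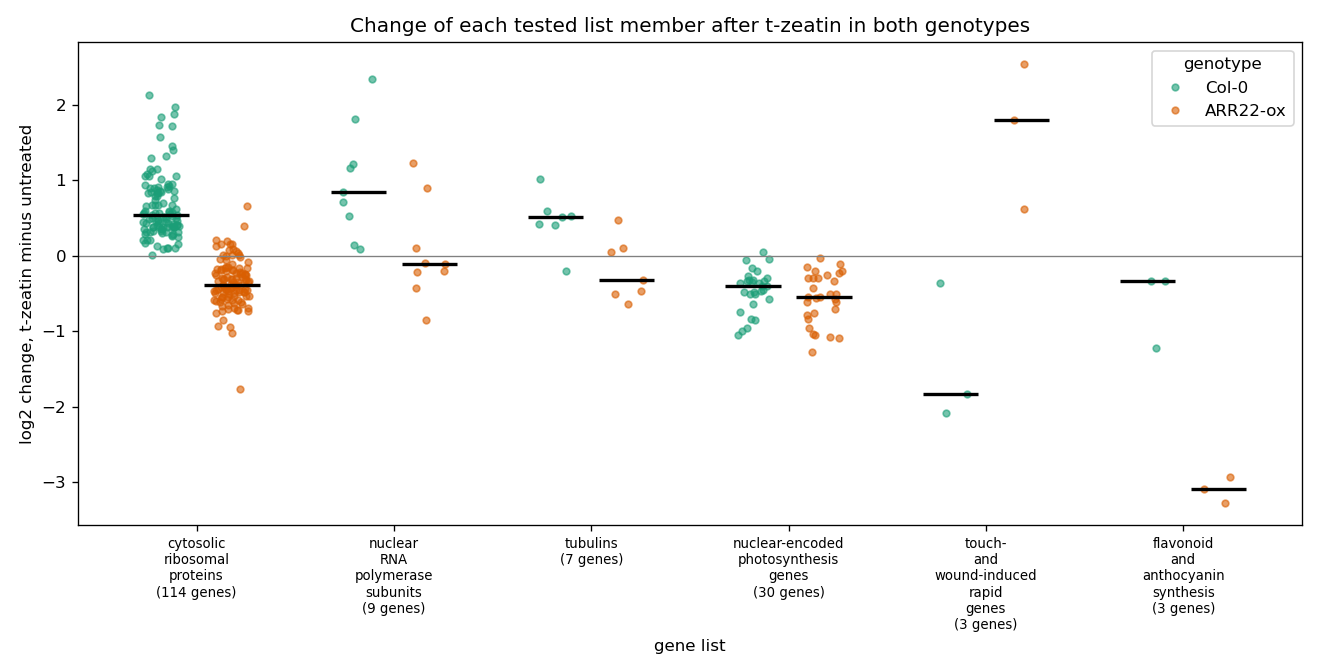
Log2 change after t-zeatin of each tested member of 6 gene lists, in Col-0 and in ARR22-ox; points are genes and black bars list medians. The ribosomal protein medians were 0.54 in Col-0 and -0.38 in ARR22-ox, those of the touch- and wound-induced genes -1.83 and 1.80, and those of the photosynthesis genes -0.39 and -0.54.

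The difference was called for 6222 probe sets, 2876 with a higher and 3346 with a lower response in ARR22-ox, and 2651 differed at least 2-fold. The responses share no array, but the same variance estimate of each probe set enters both, so their calls are not independent. A count above the chance value is thus no evidence of a shared response. Of the probe sets called in both, 978 rose in both (815 by chance for independent lists) and 978 fell in both (722), while 695 rose in Col-0 and fell in ARR22-ox (810) and 854 did the reverse (727). Of the 6113 probe sets called in Col-0, 54.3% had the same sign in ARR22-ox. The difference was called for 3863 of them: 2689 had the opposite sign in ARR22-ox, 834 a smaller change and 340 a larger change of the same sign. These counts lean towards a smaller or opposite change, because the probe sets were chosen for their Col-0 change. The named differences upward were AT5G62280 (4.90), the cell wall gene XTH18 (4.72), AT1G15010 (4.64), EXO and AT2G39980 (4.54). Those downward were AT3G28270 (-4.75), AT5G12110 (-4.23), RR16, AT1G47400 (-3.72) and AT3G52170 (-3.60). Without ARR22-ox untreated replicate 3 XTH18 differed by 4.05, and AT3G28270 differed by -5.82 without Col-0 untreated replicate 3 and by -2.53 with the offset.

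**Figure D3:**
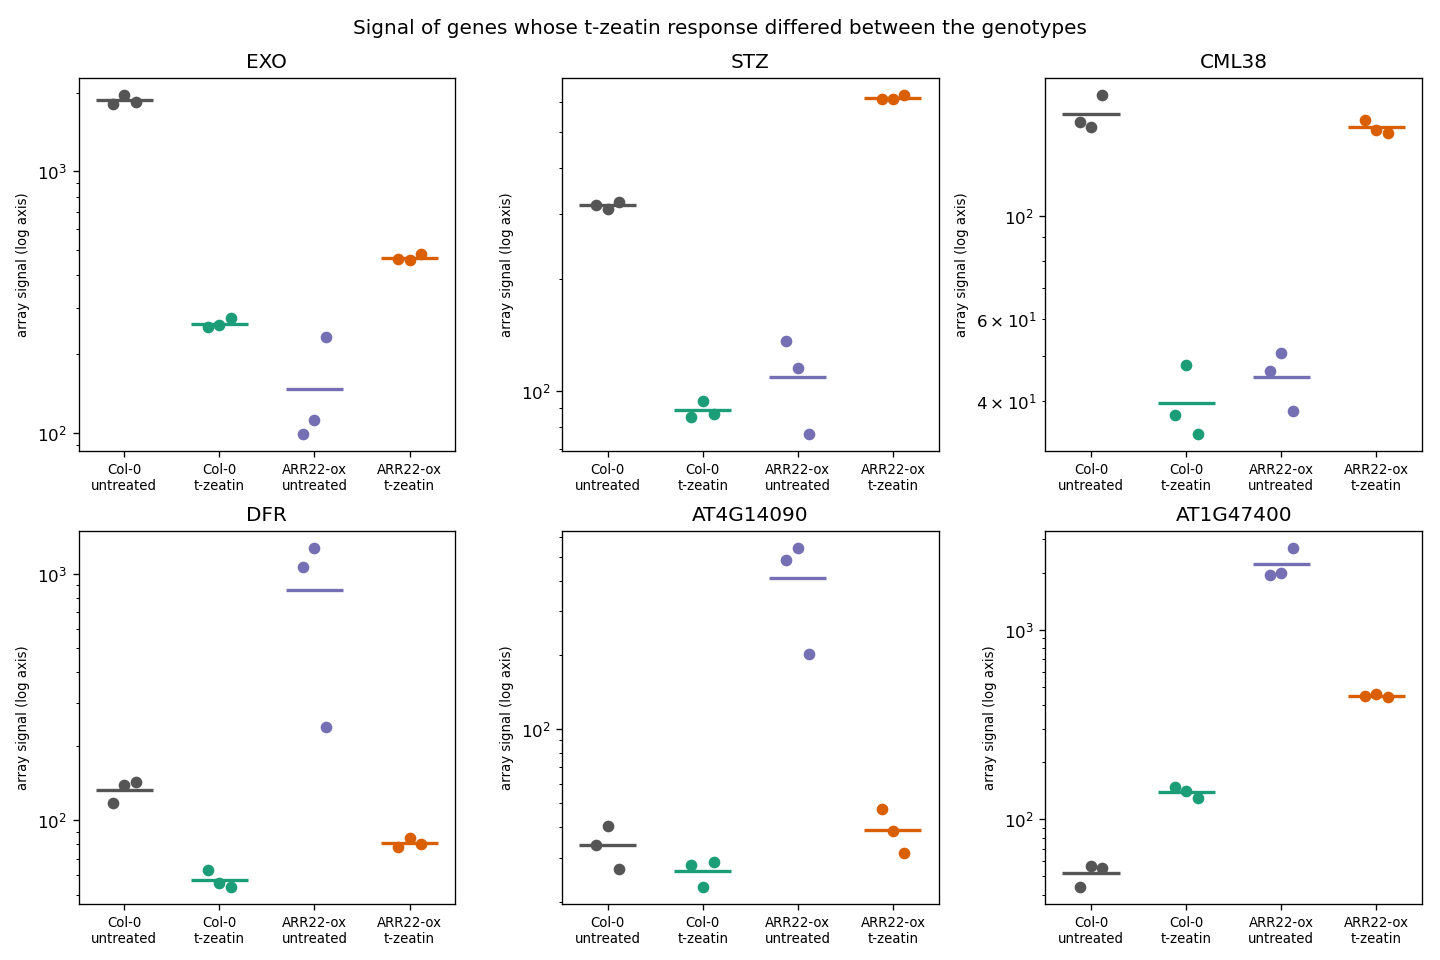
Array signal on a log axis of EXO, STZ, CML38, DFR, AT4G14090 and AT1G47400 in the 4 groups; points are the 3 arrays of a group and bars their means. STZ had means of 317 and 88.9 in Col-0 untreated and t-zeatin and of 109 and 617 in ARR22-ox; on ARR22-ox untreated replicate 3 DFR was 239 against 1066 and 1272.

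The fifth comparison asked how ARR22-ox differed from Col-0 without added hormone. It uses the same ARR22-ox untreated arrays as the ARR22-ox response, with opposite sign. It also shares the Col-0 untreated arrays with the Col-0 response. A gene or list that stood apart in an untreated group therefore appears in both comparisons and in the difference of responses. Such results are not separate evidence. Besides RR22, AT1G47400 was higher in ARR22-ox, 2208 ± 415 against 51.8 ± 7.09 (SD, n = 3; log2 difference 5.41 ± 0.13, SE; adjusted p = 1.2e-10). The tested anthocyanin genes were higher, AT4G14090 with 409 ± 182 against 33.8 ± 6.77 and UF3GT with 353 ± 161 against 36.4 ± 5.97. EXO was lower, 148 ± 73.3 against 1867 ± 77.2, and so was XTH33, a xyloglucan-modifying cell wall gene, with 12.7 ± 1.1 against 121 ± 7.2. RR16 was lower by a log2 difference of -0.66, a call lost without Col-0 untreated replicate 2 or 3 or ARR22-ox untreated replicate 1 or 2 (adjusted p up to 0.0924), with only the 6 arrays compared (0.0964) and with quantile normalization (0.0562).

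All 3 tested flavonoid and anthocyanin genes were higher in ARR22-ox (median 3.15, camera adjusted p = 0.0135, or adjusted p = 0.167 with an estimated correlation). DFR was 2.37 higher, or 3.13 without ARR22-ox untreated replicate 3, the array with the high 3'/5' ratios. All 3 tested touch- and wound-induced genes were lower (median -1.57, adjusted p = 0.0135, or adjusted p = 0.08 with an estimated correlation). So were 3 of 4 tested expansins, which loosen cell walls (median -1.22, adjusted p = 0.015, or adjusted p = 0.08 with an estimated correlation). The 2 glutaredoxin genes AT4G15660 and AT5G18600 of 3 tested were lower (adjusted p = 0.0374, or adjusted p = 0.107 with an estimated correlation), and that list missed the threshold without ARR22-ox untreated replicate 3 (adjusted p = 0.196). These counts were the same when adjusted over the list alone, a step that could hardly have lowered them. The added list of expansins and expansin-like genes had 5 lower and 2 higher of 11 and did not pass (median -0.44, adjusted p = 0.185). Its median was -0.11 without ARR22-ox untreated replicate 3. In the added lists, 91 of 114 ribosomal protein genes were higher and none lower (median 0.39, adjusted p = 2.13e-16, or adjusted p = 0.217 with an estimated correlation). All 5 xyloglucan endotransglucosylase genes were lower (median -1.48, adjusted p = 0.00816, or adjusted p = 0.217 with an estimated correlation), and the stricter filter ended that call (adjusted p = 0.107).

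Without hormone 6622 probe sets differed between the genotypes, 3342 higher and 3280 lower in ARR22-ox, and 1564 differed at least 2-fold. AT3G28270 stood at 507 ± 110 against 3.44 ± 4.36, a log2 difference of 8.02 that was 9.08 without Col-0 untreated replicate 3 and 5.22 with the offset. Further named genes that were higher were AT1G73040 (4.45), AT1G12030 (4.19), AT1G49570 (4.16), AT1G80130 (3.65), AT5G05250 (3.48) and AT5G02580 (3.36). Further named genes that were lower ranged from -4.96 (AT1G66100) to -3.20 (AT1G50040) and included AT3G06070, AT5G62280, AT5G52760, AT1G10340, AT5G57760 and AT5G12050.

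The last comparison asked how the genotypes differed after t-zeatin. It shares the t-zeatin arrays with the responses, so its results are not separate evidence from theirs either. RR16 was lower in ARR22-ox, 8.55 ± 1.42 against 244 ± 17 in Col-0 (SD, n = 3; log2 difference -4.85 ± 0.22, SE; adjusted p = 6.28e-09), and so was UGT76C2, 17.8 ± 6.71 against 209 ± 6.52 (-3.62). Both ARR22-ox means lie below the lowest kept mean, so the sizes are uncertain, and with the offset they were -3.73 and -2.97. ATC, a relative of the floral repressor TFL1, was higher, 152 ± 2.43 against 10.5 ± 5.36. JRG21, a jasmonate-regulated gene, was higher too, 659 ± 5.86 against 47.3 ± 2.13. GH9B8, an endoglucanase-family gene, was lower, 11.2 ± 7.03 against 121 ± 19.4.

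All 4 tested expansins were lower in ARR22-ox, also when adjusted over the list alone (median -2.38, camera adjusted p = 0.00222, or adjusted p = 0.0413 with an estimated correlation), among them EXPA4 with 64.2 ± 4.26 against 311 ± 37. The wider added list of expansins and expansin-like genes went both ways, with 5 lower and 2 higher of 11, and did not pass (median -0.26, adjusted p = 0.24). The touch- and wound-induced list did not pass (median 1.98, adjusted p = 0.0551), while STZ was 2.80 and CML38 1.98 higher. In all, 12 added lists passed camera and none of them with an estimated correlation. They held 109 of 114 ribosomal protein genes lower and none higher (median -0.52, adjusted p = 4.82e-20, or adjusted p = 0.0877 with an estimated correlation), 6 of 7 tubulin genes lower (adjusted p = 0.00229, or adjusted p = 0.228 with an estimated correlation) and 5 of 5 U-box ligases higher (adjusted p = 0.00116, or adjusted p = 0.0877 with an estimated correlation). Of 28 UDP-glycosyltransferases 16 were higher and 4 lower (adjusted p = 0.00657, or adjusted p = 0.0877 with an estimated correlation). Of 30 photosynthesis genes 16 were lower and 3 higher (adjusted p = 0.0156, or adjusted p = 0.0975 with an estimated correlation). The other 7 were plastid-encoded genes (18 higher and 2 lower of 64; adjusted p = 0.00684, or 0.0842 by fry), autophagy genes (5 higher of 10; 0.0156), CYP71B cytochromes P450 (5 higher of 9; 0.0178), RNA polymerase subunits (5 lower of 9; 0.0352), beta-glucosidases (6 higher and 2 lower of 10; 0.0376), glutathione transferases (5 higher and 2 lower of 8; 0.0434) and serine carboxypeptidase-like genes (8 lower and 1 higher of 13; 0.0465). With an estimated correlation these 7 had adjusted p from 0.0975 to 0.589. The stricter filter ended the calls of the last 5 (adjusted p from 0.0948 to 0.216). The serine carboxypeptidase-like list also missed the threshold without Col-0 t-zeatin replicate 2, ARR22-ox untreated replicate 1 or ARR22-ox t-zeatin replicate 2 (adjusted p from 0.0513 to 0.0714), with the offset (0.0513) and without the filter (0.108). Without ARR22-ox untreated replicate 3, which enters only the shared variance here, 35 plastid-encoded genes were higher and 7 lower of 64.

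After t-zeatin 6966 probe sets differed, 3146 higher and 3820 lower in ARR22-ox, and 1841 differed at least 2-fold. Of those called in both genotype comparisons, 1178 were higher in both (770 by chance for independent lists) and 1221 lower in both (918). These comparisons share no array but share the variance estimate of each probe set, so their calls are not independent either. A further 875 were higher untreated and lower after t-zeatin (935), and 778 the reverse (756). RR22 was 12.47 higher, or 8.02 with the offset. The remaining named genes were AT5G19890 (4.26) and AT1G49570 (3.97), which were higher, and AT5G12110 (-4.27) and AT1G14960 (-4.19), which were lower.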

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

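The tests of the RNA and labels of ARR22-ox untreated replicate 3, the test of the handling of untreated Col-0 plants, and the values of the added lists and of the differences of named genes under each alternative were chosen only after the data they rest on had been seen.

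Ribosomal protein genes rose in Col-0 and fell in ARR22-ox, a difference between genotypes with a median of -0.92, but with an estimated correlation the list passed neither for the fall (adjusted p = 0.22) nor for the difference (adjusted p = 0.0608). The tables argue against a scaling effect on bright probe sets: none of 10000 lists of 114 genes matched on signal had a median difference as low, a share of 1e-04, which is the smallest these draws can give, and their medians ran from -0.22 to 0.16. They also argue against ARR22-ox untreated replicate 3 as the source, since the median was -0.90 without it. What stays open is whether each group was grown, harvested or hybridised on its own: the labels name 0 batches that hold over 1 group, so a batch and the groups cannot be told apart. A genotype-dependent response to t-zeatin is thus a hypothesis that these arrays could not separate from such batches.

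The tested touch- and wound-induced genes, only STZ, CML38 and WRKY53 of a longer list, fell in Col-0 and rose in ARR22-ox, with a median difference of 3.87. Only 2 of these 3 members passed in Col-0. With an estimated correlation the list passed neither in Col-0 (adjusted p = 0.141) nor in ARR22-ox (0.137) nor for the difference (0.0637). The untested members of the list may have moved otherwise. Handling of the untreated Col-0 plants alone cannot account for both directions, because the rise in ARR22-ox, with a median of 1.80, contains no Col-0 array; for the fall in Col-0 it stays open. ARR22-ox untreated replicate 3 is argued against as well, with a median rise of 1.68 without it. Handling that differed from group to group cannot be told apart from the groups, since the labels name 0 batches that hold over 1 group and the untreated plants were not a mock treatment. The biological alternative, a response that depends on ARR22, was not tested apart from these.

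ARR22-ox untreated replicate 3 stood apart from its group, with a mean correlation across probe sets of 0.927 and a fitted array weight of 0.063. A Col-0 sample under the wrong label is argued against by its ARR22 signal of 3661, against at most 1.92 on Col-0 arrays. A whole t-zeatin-treated ARR22-ox sample under the wrong label is argued against by a correlation of 0.0898 across probe sets between its deviation and the ARR22-ox response; the bounds of that test were set after the value was seen, and a small admixture was not tested. Lower RNA integrity or shorter labelled product may be the source: the 3'/5' ratio of the second actin control was 3.47, against at most 1.38 on the other arrays, and those of GAPDH and ubiquitin also lay above all others. No biological explanation was tested for this array.

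Chance was examined by regrouping the arrays. In each pairwise comparison only 1 of 10 splits, the real one, gave as many calls, and the highest other gave 0 against 6113 in Col-0, 6863 in ARR22-ox, 6622 between untreated and 6966 between treated genotypes; 10 splits are too few for a share under 0.05. For the difference of responses, 1 of 100 drawn regroupings, the real one, reached 6222 calls, and the highest other gave 1365. Regroupings that mix treated and untreated arrays put the difference itself into the spread within groups, which lowers their calls. The real grouping was thus favoured from the start, and neither kind of regrouping can exclude chance.

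The following results drew attention because the test of the difference of responses, ARR22-ox minus Col-0, passed, as it did for 6222 probe sets. Among other lists, the median difference was 0.42 for plastid-encoded genes, -0.89 for tubulins, 1.43 for U-box ligases and -0.94 for RNA polymerase subunits. None of these 4 lists passed with an estimated correlation (adjusted p of 0.654, 0.411, 0.165 and 0.0608), the tubulins missed the threshold without ARR22-ox untreated replicate 3 (0.0523), and the plastid-encoded genes missed it by fry (0.0737). Single members of these lists differed by -1.44 (NRPA1), -0.59 (NRPA2), -1.33 (TUB1), -1.10 (TUB7), 2.66 (PUB22) and 3.08 (PUB23). Of genes with a named rise in Col-0, the differences were -4.18 (RR16), -1.68 (AT2G18900), -2.02 (AT3G59670), -2.36 (AT1G30960), -2.16 (AT4G04940), -2.26 (AT3G12860), -2.37 (AT5G51440), -2.67 (PPR596) and -2.34 (UGT76C2). Of genes with a named fall in Col-0, they were 4.60 (EXO), 3.02 (AT5G10695), 2.09 (AT1G76960), 1.47 (AT5G25240), 2.74 (AT2G41640), 3.23 (AT2G44500), 2.98 (AT5G58120), 4.27 (AT4G28085), 3.24 (WRKY22) and 3.91 (AT1G02660). Another named rise, AT1G10585, had a difference of 0.23 that was not called (adjusted p = 0.638). Genes named for a response were chosen for its size, and that response enters the difference, so its sign is largely set by the choice. With the offset the difference was -1.70 for AT1G30960, 2.30 for AT5G58120 and 3.59 for AT4G28085. That of AT1G30960 was -3.05 with quantile normalization.

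Of genes with a named rise in ARR22-ox, the differences were 4.21 (psaA), 4.44 (AT3G23550), 2.79 (AT5G48430), 3.46 (AT2G22880), 1.67 (AT2G38240), 3.52 (rpl16), 4.23 (AT3G60420), 4.90 (AT5G62280), 2.74 (CCR2) and 2.54 (AT5G62360). Of genes with a named fall there, they were -1.56 (AT1G22160), -2.95 (AT4G14090), -1.73 (AT5G48490), -2.55 (HIS1-3), -1.87 (DFR), -2.31 (AT5G57785), -2.59 (UF3GT), -2.03 (AT1G67750), -2.70 (AT2G20870) and -1.57 (AT5G62210). Without ARR22-ox untreated replicate 3 the difference was 3.43 for psaA, 0.93 for AT2G38240, 2.93 for rpl16, 1.76 for CCR2, -1.14 for AT5G48490 and -2.63 for DFR. That of CCR2 was 3.39 without ARR22-ox untreated replicate 1, and that of AT2G22880 was 4.06 without Col-0 untreated replicate 2. With the offset the difference was -0.85 for AT1G22160, 1.89 for CCR2 and 4.12 for AT5G62280. Quantile normalization gave 2.09 for CCR2. The call of AT2G38240 was lost without any 1 of the 6 Col-0 arrays or the 3 ARR22-ox t-zeatin arrays (adjusted p from 0.0626 to 0.0915), without the filter on dim probe sets (0.0619) and without a variance trend (0.0522). That of DFR was lost without replicate 1 or 2 of Col-0 untreated, Col-0 t-zeatin or ARR22-ox untreated, or without ARR22-ox t-zeatin replicate 1, 2 or 3 (adjusted p from 0.0504 to 0.0659).

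The genes named for the difference itself were XTH18 (4.72), AT1G15010 (4.64), AT2G39980 (4.54), AT3G28270 (-4.75), AT5G12110 (-4.23), AT1G47400 (-3.72) and AT3G52170 (-3.60). XTH18 stood at 4.05 without ARR22-ox untreated replicate 3, and AT3G28270 at -5.82 without Col-0 untreated replicate 3. With the offset AT3G28270 stood at -2.53, AT1G15010 at 3.99, AT5G12110 at -3.47 and AT3G52170 at -2.75. Of the hormone and defence genes in the fixed lists, the differences were 3.24 (GH3.3), 1.101 (WES1), 0.67 (SPY), 2.30 (PDF1.2), 1.86 (SAG101), 0.81 (COR47) and 1.45 (WRKY6). Those of the stress, cell wall and root genes were 0.98 (WRKY53), 4.37 (STZ), 3.87 (CML38), 2.86 (CML42), 3.51 (XTH33), -1.84 (EXPA4), -1.49 (EXPA15), -0.75 (EXPB3), 0.63 (AT5G18600) and 0.81 (EXPA7). With the offset the difference of XTH33 was 2.70. The call of SPY was lost without Col-0 untreated replicate 1, Col-0 t-zeatin replicate 1 or ARR22-ox t-zeatin replicate 2 or 3 (adjusted p up to 0.0724). That of EXPA7 was lost without Col-0 untreated replicate 1, Col-0 t-zeatin replicate 1 or 2, ARR22-ox untreated replicate 1 or ARR22-ox t-zeatin replicate 3 (up to 0.0788), and without the filter on dim probe sets (0.0524). That of WRKY53 was lost without Col-0 untreated replicate 1 or 2, Col-0 t-zeatin replicate 1 or 3, ARR22-ox untreated replicate 2 or ARR22-ox t-zeatin replicate 1 or 3 (up to 0.0747), and without the filter (0.0506).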

How the results depend on the processing

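The tests of the ribosomal protein list and the other added lists under each alternative, and for the ARR22 level and the type-A median those with array weights, without a variance trend or with only the 6 arrays compared, were chosen after seeing the data. The 5 counts of called probe sets stayed within 1.5 times their values under every alternative run, and the fit with only the 6 arrays compared was not run for the difference, which needs all 4 groups. Leaving out 1 array gave 5087 to 8172 calls in Col-0, 5840 to 8335 in ARR22-ox, 5563 to 8117 for the difference, 5567 to 8392 for untreated and 6093 to 8813 for treated genotypes, each highest without ARR22-ox untreated replicate 3. The ARR22 level (8.11 with the offset) and the type-A median, which rests on RR16 alone in the main fit, kept direction and call under the alternatives run, although in ARR22-ox the type-A median went from -1.01 to -0.54 with the offset and -0.73 without ARR22-ox untreated replicate 3. Without the filter ARR15 joined RR16 in that median. The call was then that of the member with the lowest adjusted p. ARR15 itself was not called in ARR22-ox there (limma adjusted p = 0.137). Neither the ARR22 level nor the type-A median has a value under the stricter filter, which drops the probe sets of RR22 and RR16. Without a variance trend or with only the 6 arrays compared, the ARR22 level and the type-A median cannot change. Only their calls were tested there.

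The number of fixed lists past the test moved most, and the cause was not tested except where fewer genes remain in a list. In Col-0 it was 1, and became 2 without the filter, 0 with the stricter filter, 0 with an estimated correlation, 5 with fry and 1 to 2 with 1 array left out, 2 without ARR22-ox untreated replicate 3. In ARR22-ox it was 2, and became 4, 0, 0 and 5 under the same settings, and stayed 2 with 1 array left out. For the difference it was 1, and became 4, 0, 0 and 5, then 2 with array weights and 1 to 2 with 1 array left out, 2 without ARR22-ox untreated replicate 3. For untreated genotypes it was 4, and became 1 with the stricter filter, 0 with an estimated correlation and 3 to 4 with 1 array left out, 3 without ARR22-ox untreated replicate 3. For treated genotypes it was 1, and became 3 without the filter, 3 with fry and 1 to 2 with 1 array left out, 2 without Col-0 t-zeatin replicate 2 or ARR22-ox t-zeatin replicate 1 or 2. With an estimated correlation the ribosomal protein medians, -0.38 in ARR22-ox and -0.92 for the difference, no longer passed (adjusted p of 0.22 and 0.0608); over the other alternatives they passed.

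Of 4110 alternative values of 211 results of single named genes, 3987 kept direction and side of the threshold, 120 lost the call and 3 changed sign. Many of these values could not change direction. The filters, the variance trend and a fit to only the arrays compared leave the log2 change of a gene as it was. Leaving out an array that a pairwise comparison does not use does so too. Such settings test only the call, so the tally overstates how well directions held. Under the stricter filter only 138 of the 211 have a value, and the rest count neither as kept nor as lost. Most results not called in the main fit were left out of this tally. Among these, without ARR22-ox untreated replicate 3 the difference of responses of GI turned from 0.28 to -0.53, and its untreated genotype difference from -0.54 to 0.26. The 3 sign changes in the tally were those of UGT76C2 in ARR22-ox, 0.11 and not called: -0.0356 with quantile normalization, -0.23 without ARR22-ox untreated replicate 1 and -0.18 without ARR22-ox t-zeatin replicate 3. With 1 array left out it ran from -0.23 to 0.42, and the cause was not tested. Dim signals limit the size of a log2 change, as for RR22 and AT3G28270.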

Other observations

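The lists and genes tested below for ribosome assembly, iron and the hour of harvest were chosen after the main results had been seen, and the members that had been seen were left out of each test.

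Histone genes were higher in ARR22-ox without hormone: 7 of 8 tested, among them, picked after the values were seen, HTB1 by 0.80 and AT2G28720 by 0.96 (median 0.75, camera adjusted p = 0.00495, or adjusted p = 0.234 with an estimated correlation). Of 8 glutathione transferase genes 5 were higher and 1 lower (median 0.80, adjusted p = 0.0268, or adjusted p = 0.296 with an estimated correlation), with GSTU25 1.82 and GSTU22 1.63 higher, picked in the same way; the stricter filter ended that call (adjusted p = 0.136). ARR15, a second type-A response regulator, lay below the filter and was examined after its values were seen. Its signal was 12.1 ± 0.43 untreated and 147 ± 10.8 after t-zeatin in Col-0, and 10.1 ± 2.29 and 6.17 ± 3.74 in ARR22-ox (SD, n = 3 arrays per group). As 3 of these 4 means lie below the lowest kept mean of 24.3, no size is given for its changes.

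AT3G12860 and AT4G04940, both known as ribosome assembly genes, were among the 10 largest rises in Col-0, which suggested that such genes rose as a group. Of 22 other ribosome biogenesis factors, all 22 rose in Col-0, with a median of 1.299 and a range from 0.76 to 2.41 (unadjusted camera p = 6.2e-17, or unadjusted p = 0.000956 with an estimated correlation). In ARR22-ox 9 rose and 2 fell, with a median of 0.10, and the list did not pass camera. Without ARR22-ox untreated replicate 3, 7 rose and 6 fell there, with a median of 0.16. The difference of responses had a median of -1.33 with 21 lower (unadjusted p = 0.00314 with an estimated correlation). The values are in line with a group rise in Col-0, as a hypothesis found and tested on the same arrays, and a batch that follows the groups stays open.

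AT1G47400 and AT5G05250 were among the largest rises in ARR22-ox untreated, so a wider difference of genes induced by iron deficiency might underlie them. Without those and PYE, whose value had also been seen, the 3 other tested members had differences of -0.28, -0.24 and 0.73, a median of -0.24, and with PYE, which was 1.59 higher, the median was 0.25. A median under 0.1 had been set in advance to argue against the idea, and the value met that bound. Without ARR22-ox untreated replicate 3 the median was -0.48, with 1 member higher and 2 lower, which also goes against the idea. The bound was judged wrong only after the value was seen: the 3 members went both ways, AT3G07720 being higher past the threshold, and called genes had been left out of the list, so the question stays open.

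GI, a clock gene that peaks late in the day, was higher after t-zeatin in ARR22-ox (1.60, or 0.79 without ARR22-ox untreated replicate 3, a call lost with only the 6 arrays compared, adjusted p = 0.0795, the highest of its alternatives) and in Col-0 (1.32, a call lost without any array outside ARR22-ox untreated or without the filter, adjusted p up to 0.102), so treated plants might have been harvested later. Of 8 changes of 4 other evening or morning genes, 3 passed the test against that direction and 1 in its favour. The evening genes COR27 and AT4G33980 fell in Col-0, by 1.05 and 1.01 on the log2 scale, and the morning gene AT5G52660 rose in ARR22-ox by 0.32. AT4G33980 rose in ARR22-ox by 0.67. These values go against a later hour as the sole source only if each gene moves with the hour in the assumed direction. The labels do not give the hour, and an effect of t-zeatin on these genes was not separated from it, so the question stays open.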
